A study of Drosophila melanogaster with 4 samples.

How the data were processed

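Whole wing imaginal discs were dissociated and profiled with the 10x Chromium 3' platform, which captures the 3' end of polyadenylated RNA and tags each molecule with a UMI. Per the labels' protocols, the 2 control libraries used chemistry version 2 and a collagenase-TrypLE dissociation. The mutant libraries used version 3.1, with the same cocktail for replicate 1 and 0.25% trypsin for replicate 2. Dead cells and doublets were removed by fluorescence-activated sorting, per the series' design text, and myoblasts carrying Him-GFP were sorted out of all libraries but control replicate 1. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 2.2 for controls and 6.1.0 for mutants per the submitters' processing notes. The file headers of the mutant matrices instead name cellranger 6.1.1 (filtered barcodes) and Cell Ranger 4 (all barcodes). The genome build and gene annotation are not given in the sources used here. Whether intronic reads were counted is also not given, and a difference in that setting would move counts of intron-rich genes. The filtered mutant matrices held 95.5% and 94.3% of the UMIs of the matrices of all barcodes, with 0 differing entries. The corresponding control matrices of all barcodes were not used here, and free RNA in droplets was not compared between groups. The control tables list 17509 genes, all of which also occur among the 17772 genes of the mutant tables, and the remaining genes held 0 UMIs. Genes were joined by FlyBase identifier, and 17389 identifiers had a symbol in the gene name table used.

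Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called with scrublet in scanpy 1.11.5 at an expected rate of 0.06, and the calls (0 and 44 in controls, 39 and 0 in mutants) were removed. Such low numbers leave residual doublets possible. Counts per cell were scaled to 10000 and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.5 gave clusters of all cells. Clusters were named from fixed markers. A cluster counted as epithelium-like at a mean marker level of 6.0 or more on the log2 scale, with myoblast, hemocyte, glia and fat body scores under 1.0. Tracheal and neural scores were no part of this rule, and those types were told apart in the second clustering. The bounds were set after the data were seen. Most epithelium-like clusters of this first step held cells of nearly 1 genotype only. In a mixed cluster that stayed unnamed were 2.55% and 0.311% of control cells and 0 and 0.00858% of mutant cells.

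Epithelium-like cells were clustered again at resolution 1.0 after scaling genes within each library and leaving out 13 program gene lists, ribosomal protein, mitochondrial and ribosomal RNA genes and Ets21C. The program lists left out cover the ligand, JNK, JAK/STAT, apoptosis, cell cycle, ecdysone, glycolysis, matrix, heat shock, sex and EGFR genes. The cluster highest for the markers puc, Mmp1, Ilp8, upd3, rgn and Gadd45 was called blastema-like; all 6 were detected. Its leading genes by fold also included CG17124, tnc and wun2, which are not reported as results. Another cluster led by Ilp8, with 8.82% and 8.16% of control and 1.19% and 0.121% of mutant epithelium, stayed unnamed and counted as other epithelium. A pouch-like cluster was also led by Ilp8, with a blastema marker score of 0.41 on the log2 scale against 0.13 in the unnamed one, and it held 6.09% and 8.21% of control and 8.46% and 5.97% of mutant epithelium, counted as other epithelium too. Tracheal-like and neural-like clusters were left out of both epithelial classes.

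Raw UMI counts were summed per library and class, since libraries and not cells are replicates. The blastema-like sums held 2055726 and 4018260 UMIs in controls and 2194965 and 805337 in mutants, and those of other epithelium 47525713, 201341658, 167215572 and 248658345. A count of 0 in a class allows 3 counts of its total, for example 3.73 CPM in blastema-like cells of mutant replicate 2. Intervals and such limits cover counting error only. Each sum was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with TMM scaling, its filter on low counts and Benjamini-Hochberg adjustment at 0.05. CPM values use the scaled totals of the fit they belong to. The SE printed after ± is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is an approximation, which at counts near 0 can be smaller than counting error. The same SE is the unit where departures are given in squared SE. The genotype was compared in epithelium-like, blastema-like and other epithelial sums of the 4 libraries. The class effect in controls and the class by genotype interaction came from 1 fit of 8 sums with library as block. In that fit the prior degrees of freedom of the spread were estimated as infinite, which makes its p-values too small. All 4 combinations of the edgeR options legacy and robust were therefore fitted after the data were seen, and adjusted p-values with legacy set to FALSE are printed for it.

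The tests were tried on counts simulated from the real libraries with 200 changed genes. For the epithelium comparison, 85%, 74% and 26% of genes changed by 2 on the log2 scale were found as the spread between genes of the simulated dispersion grew, with 5.06%, 3.06% and 7.14% false calls over 10181, 10183 and 10129 genes. For the interaction the corresponding values were 83%, 75% and 72%, with 7.97%, 9.23% and 33.1% false calls over 8750, 8758 and 8757 genes. With legacy set to FALSE the interaction test found 80%, 69% and 43%, with 0.885%, 2.20% and 11.1% false calls. Of genes changed by 1 on the log2 scale, the epithelium test found 65%, 21% and 0%. The interaction test with legacy set to FALSE found 32%, 20% and 5% of those. The real epithelium fit had 3.78 prior degrees of freedom, nearest to the widest simulated spread, of 4. It called 5781 of 10420 genes, far more than the 200 changed evenly up and down in the simulations. The simulated rates may therefore not hold for that comparison.

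A total of 21 gene lists, the marker genes, the tests, the rule for named genes and the alternatives listed first in the last paragraph were fixed before the data were examined. The lists cover regeneration ligands and proteases, JNK and stress response, JAK/STAT pathway, apoptosis, S phase, G2 and mitosis, cell cycle arrest, ecdysone response and timing, glycolysis, extracellular matrix, heat shock and dissociation stress, sex composition, Ets family and EGFR feedback, wing pouch patterning, hinge and notum patterning, Wnt and Hippo targets, immune signalling, and markers of hemocytes, myoblasts, trachea and neural or sensory precursors. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1). List members whose symbol differed from the gene name table were matched through a table of synonyms. Named genes were, for epithelium and the interaction, the 6 with the largest log2 fold change each way among those past 0.05 with a mean of at least 50 CPM in the higher group, both mutant libraries on 1 side of both controls and at least 10 UMIs in every library. For each list they were up to 4 members past 0.05 with the smallest p, or up to 2 with the highest mean where none passed. The text names most of these.

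Alternatives were DESeq2 1.42.0, library totals, no low-count filter, each library left out, the replicate number as a block, at least 1000 genes per cell, at most 20% mitochondrial UMIs, doublet calls kept, cells thinned to 2000 UMIs, other resolutions, genes scaled over all libraries, and program genes kept in the clustering. Added after the data were seen were the edgeR option sets and a fit without the epithelial clusters whose median depth was 0.269, 2.21 and 2.45 relative to their own libraries. Gene positions and intron lengths came from the BDGP6.54 annotation, matched by gene identifier.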

Results

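Single-cell RNA profiles were collected from regenerating wing imaginal discs of Drosophila melanogaster, the larval epithelial sacs that form the adult wing and thorax. Tissue was ablated in the future wing region by GAL4-driven expression of eiger, a tumour necrosis factor ligand that triggers JNK signalling and cell death, for 40 h at 30 °C from day 7. Larvae were otherwise kept at 18 °C, and discs were taken 24 h into regeneration. The 4 libraries fall into 2 groups of 2, control and mutant for Ets21C, which encodes an ETS-domain transcription factor induced by JNK signalling. The control libraries held 10768 and 6476 barcodes with 222181584 and 229994345 UMIs (unique molecular identifiers, each standing for 1 captured transcript). The mutant libraries held 8409 and 16657 barcodes with 201703366 and 274889137 UMIs. After filtering, 10767 and 6432 control cells and 5657 and 11656 mutant cells remained, with median UMIs of 18595, 27964, 26243 and 20079. Controls were made with 10x chemistry version 2 and mutants with version 3.1, so chemistry and software cannot be told apart from genotype in any direct comparison of the groups. The labels give the 2 controls different genotypes, replicate 1 without and replicate 2 with Him-GFP, so these came from different animals. For the mutants nothing in the labels says that replicates came from separate cultures or animals, and their dissociation differed. The p-values therefore measure the spread between these libraries, which mixes such differences and may be technical.

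Ets21C (FBgn0005660) lies on chromosome 2L from 544925 to 552923 on the minus strand of the BDGP6.54 annotation. Over all barcodes it gave 372 and 1278 UMIs in the control libraries and 1416 and 623 UMIs in the mutant libraries. Among blastema-like cells, the regenerating cells described further on, it gave 87 and 186 UMIs in controls and 103 and 21 UMIs in mutants. Its level there was 42.3 (95% exact Poisson interval 33.9 to 52.2) and 46.3 (39.9 to 53.4) CPM, the usual scaling of UMI counts by the total of the class, in controls. The mutant values were 46.9 (38.3 to 56.9) and 26.1 (16.1 to 39.9) CPM. The Ets21C transcript was thus detected in both genotypes, with a log2 fold change of -0.05 ± 0.27 (SE) in blastema-like cells (adjusted p = 0.908) and -0.20 ± 0.57 in all epithelium (adjusted p = 0.781), from 2 libraries per group. A 3' tag outside the part of a gene that a mutation changes checks nothing. The genotype label, Ets21C-/-, does not say what was changed, so these counts do not check the labels. In epithelium the value was -1.30 without mutant replicate 1, then past the threshold, 0.37 without mutant replicate 2 and 0.07 without control replicate 2, and in blastema-like cells it was 0.21 without mutant replicate 2.

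Most cells were disc epithelium or its associated myoblasts. Myoblast-like cells, defined by markers such as twi and Him, made up 73.7% (95% exact binomial interval 72.9 to 74.5) of cells in control replicate 1, which had no Him-GFP sort to remove them. They made up 11.9% in control replicate 2, 14.2% in mutant replicate 1 and 0.129% in mutant replicate 2, all sorted. With doublet calls kept, the share of mutant replicate 1 was 0.369%, because its myoblast cluster was then of mixed identity and unnamed. Epithelium-like cells numbered 2414 and 5567 in controls and 4799 and 11615 in mutants, and hemocyte-like cells made up 1.33% and 1.24% of control cells and 0.937% and 0.214% of mutant cells. The median mitochondrial share of UMIs was 1.18% and 1.41% in controls and 4.09% and 4.80% in mutants. Before filtering, 1587 and 2651 mutant barcodes and 0 control barcodes had under 500 genes. Blastema-like cells, a single epithelial cluster with the highest level of the 6 blastema markers, made up 4.78% (115 cells) and 2.21% (123 cells) of control epithelium. They made up 2.01% (96 cells) and 0.250% (29 cells) of mutant epithelium. The exact binomial intervals of control replicate 2 (1.84 to 2.63) and mutant replicate 1 (1.63 to 2.45) overlap, and 2 libraries against 2 cannot give a two-sided exact permutation p under 0.333. With at most 20% mitochondrial UMIs the order of these libraries turned, at 1.74% and 2.44%. With genes scaled over all libraries together, the mutant shares were 1.42% and 0.0432%.

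The genotype comparison in epithelium asked how gene expression across the regenerating disc differed in Ets21C mutants. Steroid hormone response genes were higher in mutant epithelium: of 19 measured genes of ecdysone response and developmental timing, 16 rose, 0 fell and 3 did not pass. Blimp-1, an ecdysone-induced transcriptional repressor, was at 0.163 and 0.0851 CPM in controls and 57.9 and 169 CPM in mutants, a log2 fold change of 10.05 ± 0.78. The nuclear receptor gene Hr4 rose from 0.980 and 0.425 CPM to 68.4 and 259.9 CPM. The host RNA of the let-7 microRNA cluster, which times late larval development, rose by 7.49 ± 0.36 on the log2 scale. The early ecdysone genes Eip75B, Eip74EF and Eip78C rose by 2.72 ± 0.13, 2.92 ± 0.15 and 3.71 ± 0.21. Adjusted over the list alone, 16 genes were higher and 1 lower. The limma camera test placed the list above other genes (adjusted p = 9.62e-12 with a preset correlation, adjusted p = 0.491 with an estimated correlation).

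**Figure D1:**
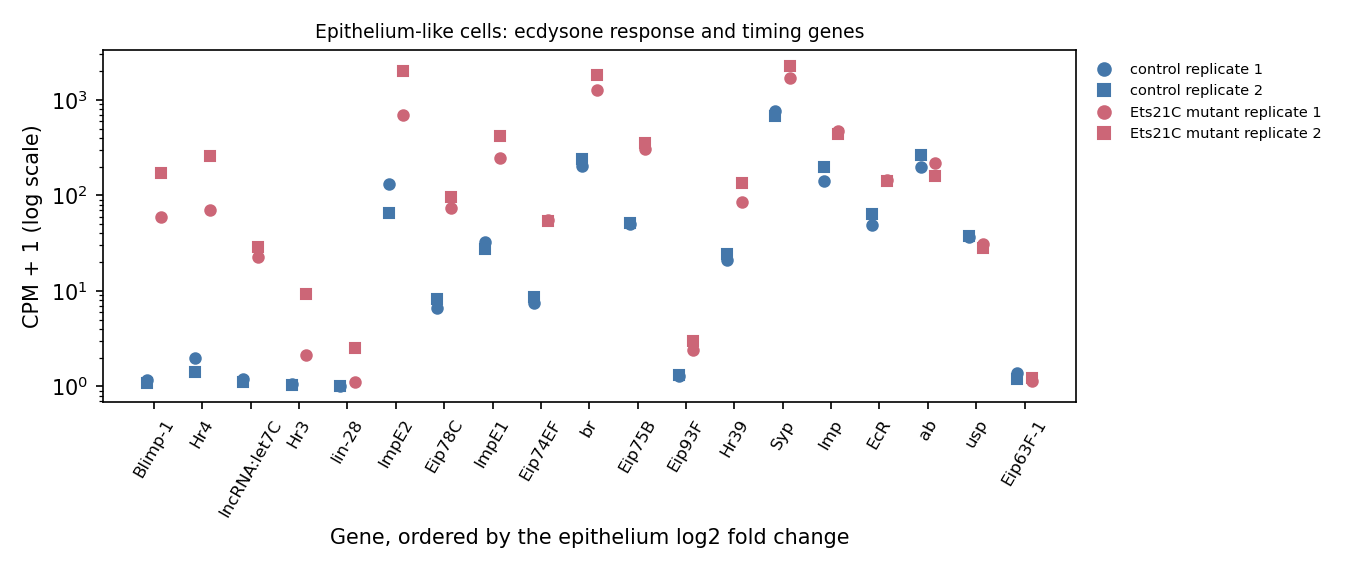
Level of each measured gene of the ecdysone response and timing list in epithelium-like cells, as CPM plus 1 on a log axis, with 1 point per library (circles for replicate 1, squares for replicate 2). Of the 19 genes, 16 were higher in the mutant libraries at an adjusted p under 0.05, and usp, ab and Eip63F-1 did not pass.

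Across all genes in epithelium, 5781 of 10420 tested passed an adjusted p of 0.05, with 3218 higher and 2563 lower in mutants. Besides Blimp-1 and Hr4, the genes with the largest rises under the fixed rule were mt:srRNA, pre-rRNA:CR45845, CG34247 and Hsp70Ab. The mitochondrial ribosomal RNA mt:srRNA rose by 6.75 ± 0.77 and the ribosomal RNA precursor pre-rRNA:CR45845 by 5.60 ± 0.30, in libraries whose mitochondrial shares also differed, as given above. The largest falls were in CG5390, l(2)34Fc, Spn47C, Aldh, RpS14b and Uhg7. CG5390, a gene of the serine protease family, stood at 284 and 302 CPM in controls and 11.1 and 15.2 CPM in mutants (-4.48 ± 0.20). The serpin gene Spn47C changed by -2.66 ± 0.19, and Aldh, an aldehyde dehydrogenase gene, by -2.98 ± 0.48. RpS14b has a near-identical copy, RpS14a, and its value (-2.26 ± 0.38) is uncertain. Adjusted p-values of these 12 genes lay between 0.00101 and 0.00648 (edgeR, Benjamini-Hochberg).

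Several lists of signalling genes had more higher than lower members in mutant epithelium. Of 8 measured genes of the Ets family and EGFR feedback, 7 rose and 1 fell, and adjusted over the list alone the counts were also 7 and 1. Egfr, the epidermal growth factor receptor, rose by 2.41 ± 0.12, its feedback inhibitor kek1 by 1.42 ± 0.15, and the ETS factor genes pnt and aop by 1.45 ± 0.14 and 1.06 ± 0.12 (list adjusted p = 0.00245 with a preset correlation, adjusted p = 0.624 with an estimated correlation). Of 11 genes of the list named Wnt and Hippo targets, 9 rose and 0 fell, as also when adjusted over the list alone. That list also holds the pathway genes ft, ds and wts, so it is no measure of targets alone. The growth regulator Myc rose by 2.45 ± 0.15, kibra by 2.48 ± 0.16, the secreted Wnt inhibitor Notum by 2.02 ± 0.15 and the polarity gene crb by 2.87 ± 0.23 (list adjusted p = 4.24e-08 preset, adjusted p = 0.491 with an estimated correlation). Of 8 JAK/STAT pathway genes, 5 rose and 1 fell, the same when adjusted over the list alone, with Stat92E at 2.18 ± 0.19 and the kinase gene hop at 1.75 ± 0.19 (list adjusted p = 0.0879 preset). Of 19 regeneration ligands and proteases, 12 rose and 3 fell, as also when adjusted over the list alone. The EGFR ligand gene vn rose by 2.21 ± 0.18, the BMP ligand gene dpp by 1.43 ± 0.16, Mmp2 by 3.19 ± 0.27 and its inhibitor Timp by 2.39 ± 0.29 (list adjusted p = 0.0440 preset, adjusted p = 0.624 with an estimated correlation). Of 23 JNK and stress response genes, 7 rose and 3 fell, the same adjusted over the list alone, with the kinase gene msn at 3.0 ± 0.20 and the AP-1 subunit kay at 1.38 ± 0.19 (list adjusted p = 0.395 preset). Against random lists matched on intron length and level, a comparison chosen after the data were seen, the list medians stood at percentiles 70.25 for EGFR feedback, 99.64 for Wnt and Hippo, 23.2 for JAK/STAT, 21.78 for ligands and 1.04 for JNK and stress genes.

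Cell cycle genes moved in both directions. Of 12 S phase genes, 2 rose and 9 fell, as also when adjusted over the list alone. The replicative helicase genes Mcm6 and Mcm2 changed by -1.12 ± 0.13 and -0.93 ± 0.12, while E2f1 and CycE, which drive S phase entry, rose by 1.55 ± 0.14 and 1.65 ± 0.19 (list adjusted p = 0.0440 preset, adjusted p = 0.787 with an estimated correlation). Of 13 genes of G2 and mitosis, 2 rose and 4 fell (1 and 4 adjusted over the list alone), with Cdk1 at -1.04 ± 0.13 and aurB at -0.99 ± 0.13 (list adjusted p = 0.0879 preset). Of 5 cell cycle arrest genes, 1 rose and 1 fell (1 and 0 adjusted over the list alone; list adjusted p = 0.911 preset). The call of dap (0.77 ± 0.18) was lost without control replicate 1 (0.52) or mutant replicate 1 (0.58). That of Wee1 (-0.52 ± 0.17) was lost without control replicate 1 (-0.66), control replicate 2 (-0.50) or mutant replicate 2 (-0.41). Of 12 apoptosis genes, 4 rose and 1 fell, the same over the list alone, and the pro-apoptotic gene hid rose by 1.82 ± 0.25 (list adjusted p = 0.763 preset). Of 14 glycolysis genes, 4 rose and 6 fell, the same over the list alone, with sima, the hypoxia-inducible factor, at 1.71 ± 0.19, Hex-A at 1.48 ± 0.30, Gapdh2 at -0.83 ± 0.14 and PyK at -0.66 ± 0.12. The glycolysis list had a median of -0.32 and a mean of 0.02, with opposite signs (list adjusted p = 0.509 preset).

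Wing pouch genes and hinge and notum patterning genes were mostly higher in mutant epithelium, and extracellular matrix genes moved in both directions. Of 22 wing pouch patterning genes, 16 rose and 1 fell, and of 15 hinge and notum patterning genes 13 rose and 0 fell, with the same counts adjusted over each list alone. The BMP-binding gene cv-2 rose by 2.37 ± 0.13, rn by 2.45 ± 0.21, the Notch ligand gene Delta by 2.12 ± 0.25 and the Yorkie partner sd by 1.33 ± 0.14 (list adjusted p = 5.90e-05 preset, adjusted p = 0.491 with an estimated correlation). The zinc finger genes tsh, zfh2 and ush rose by 2.10 ± 0.14, 2.2 ± 0.31 and 1.79 ± 0.19, and mirr by 1.19 ± 0.12 (list adjusted p = 0.00103 preset, adjusted p = 0.491 with an estimated correlation). Of 9 extracellular matrix genes, 5 rose and 2 fell, the same over the list alone. The laminin genes LanB1 and LanB2 rose by 1.96 ± 0.17 and 1.48 ± 0.17, and the integrin genes mys and if by 1.68 ± 0.17 and 2.73 ± 0.24 (list adjusted p = 0.0794 preset). The lower members, named after their values were seen, were SPARC, a collagen-binding matrix protein gene (-2.03 ± 0.45), and the collagen IV gene vkg (-3.15 ± 1.07), the latter at 2.68 and 0.994 CPM in controls, in libraries whose hemocyte markers differed as well. The SPARC call was lost without mutant replicate 2 (-1.88), and its value was -1.23 without control replicate 1. The vkg call was lost without control replicate 1 (-2.32), control replicate 2 (-3.76) or mutant replicate 2 (-2.35), with at most 20% mitochondrial UMIs, without shallow or deep clusters and with a robust prior, and its value was -5.20 without mutant replicate 1.

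Stress, sex and marker genes of other cell types differed between the groups as well. Of 15 heat shock and dissociation stress genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone). Hsp70Ab rose by 5.33 ± 0.43, Hsp70Aa by 3.51 ± 0.48 and Hsp68 by 1.31 ± 0.22, of which the Hsp70 genes are near-identical copies whose reads may be split (list adjusted p = 0.0113 preset, adjusted p = 0.762 with an estimated correlation). Of the 2 dosage compensation RNAs, made in males, roX2 rose by 1.71 ± 0.21 and roX1 did not pass, as also over the list alone (list adjusted p = 0.324 preset). Of 7 neural and sensory precursor markers, 5 rose and 0 fell, the same over the list alone, with elav at 1.56 ± 0.15 and neur at 1.89 ± 0.21 (list adjusted p = 0.0598 preset). Of 8 immune signalling genes, 3 rose and 1 fell, the same over the list alone, with the peptidoglycan receptor PGRP-SA at -1.57 ± 0.24 (list adjusted p = 0.911 preset). Hemocyte markers gave 2 higher and 3 lower of 7 (2 and 4 over the list alone; list adjusted p = 0.324 preset), with the hemocyte receptor gene NimC1 at 0.254 and 0.744 CPM in controls and 0.0347 and 0.00834 CPM in mutants, a call lost without control replicate 2 (log2 fold change -3.61). Myoblast markers gave 2 higher and 3 lower of 8 (2 and 4 over the list alone; list adjusted p = 0.667 preset). Among them stumps was at 7.80 and 2.15 CPM in controls and 0.694 and 0.175 CPM in mutants, a call lost without control replicate 1, the unsorted library (-2.36), and without mutant replicate 2 (-2.86). Free RNA in droplets was not measured in both groups, so levels of a few CPM of such markers are not read as expression in epithelium. Tracheal markers gave 2 higher and 1 lower of 5 (3 and 1 over the list alone; list adjusted p = 0.778 preset), with the cuticle gene Gasp at -1.02 ± 0.15. In the fifth of genes with the longest introns 1287 were higher and 108 lower in mutants, with a median log2 fold change of 1.33. Against the random lists matched on intron length and level, the medians of the pouch and hinge lists stood at percentiles 76.68 and 61.85, and those of the heat shock and ecdysone lists at 98.86 and 100. The JNK and stress list lay below its matched lists (median 0.063 against a central 95% of 0.17 to 1.53), the S phase list stood at 0.67 and the hemocyte and myoblast markers at 0, while the other lists lay between 11.77 and 90.07 (the sex list of 2 genes was not compared). The 5781 calls became 2634 without control replicate 1 and 2597 without control replicate 2.

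The comparison in blastema-like cells, which the series title names, asked what Ets21C mutant cells express at the site of regeneration. The unpaired ligand genes of the JAK/STAT pathway were far lower in mutants. The gene upd1 gave 91 and 174 UMIs in controls and 2 and 0 UMIs in mutants, and upd3 gave 85 and 224 against 4 and 2. The last gene also served to name the class. Pooled over libraries and relative to class totals, controls exceeded mutants by 65.4 times for upd1 (95% exact interval 17.9 to 543, counting error only) and 25.4 times for upd3 (11.6 to 69.9). The count of 0 for upd1 in mutant replicate 2 allows up to 3.73 CPM. PGRP-SA fell from 89.1 and 92.9 CPM to 3.35 and 1.32 CPM (-5.01 ± 0.33), and aspr, an epidermal growth factor repeat protein gene, from 38.2 and 26.1 CPM to 0.958 and 0 CPM, a ratio of control to mutant UMIs of 47.4 (12.9 to 394). Ecdysone response genes were higher: Eip75B by 3.60 ± 0.19, br by 3.34 ± 0.26, ImpE2 by 4.41 ± 0.38 and Hr39 by 2.73 ± 0.24.

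In blastema-like cells 2518 of 6531 genes passed, with 1711 higher and 807 lower in mutants (edgeR, Benjamini-Hochberg 0.05). DESeq2 called 1643 genes (1301 higher, 342 lower), library totals in place of TMM gave 2888 (1589 higher, 1299 lower), and genes scaled over all libraries in the clustering gave 1426. Of 17 ligands and proteases, 6 rose and 6 fell, the same adjusted over the list alone. Mmp2 and vn rose by 2.76 ± 0.29 and 3.36 ± 0.26 (list adjusted p = 0.530 preset). The list of 15 measured ecdysone and timing genes had 13 higher and 0 lower, the same over the list alone (list adjusted p = 1.86e-09 preset, adjusted p = 0.210 with an estimated correlation). JNK and stress genes had 10 higher and 2 lower of 23, the same over the list alone, with msn at 3.36 ± 0.26 and the nuclear receptor gene ftz-f1 at 2.32 ± 0.29 (list adjusted p = 0.379 preset). The 23 include puc, rgn and Gadd45, which served to name the class. EGFR feedback genes had 7 higher and 0 lower of 8, the same over the list alone, with kek1 at 2.68 ± 0.17 and sty at 1.77 ± 0.21 (list adjusted p = 0.00401 preset, adjusted p = 0.655 with an estimated correlation). The Wnt and Hippo list had 9 higher and 0 lower of 11, the same over the list alone, with the Wnt feedback gene nkd at 2.79 ± 0.15 and the protocadherin gene ds at 2.82 ± 0.19 (list adjusted p = 1.86e-09 preset, adjusted p = 0.210 with an estimated correlation). Pouch genes had 14 higher and 0 lower of 22 (16 and 0 over the list alone), with Delta at 3.05 ± 0.21 and the T-box gene bi at 1.89 ± 0.17 (list adjusted p = 9.13e-06 preset, adjusted p = 0.265 with an estimated correlation). Stat92E was at 2.28 ± 0.24, PCNA at -1.03 ± 0.19 and aurB at -1.17 ± 0.18, while hid was at 1.59 ± 0.29. Hsp70Ab, at 5.09 ± 0.45, and roX2, at 2.06 ± 0.29, moved with genotype here too. Heat shock genes had 9 higher and 0 lower of 11 (9 and 1 over the list alone; list adjusted p = 0.0263 preset, adjusted p = 0.655 with an estimated correlation). Neural and sensory precursor markers had 3 higher of 3 (median 2.69; list adjusted p = 0.0263 preset, adjusted p = 0.615 with an estimated correlation), and matrix genes 5 higher and 1 lower of 7 (list adjusted p = 0.0263 preset, adjusted p = 0.690 with an estimated correlation). Tracheal markers had 3 higher and 0 lower of 4 (list adjusted p = 0.219 preset) and myoblast markers 2 and 0 of 4 (list adjusted p = 0.390 preset), and the neural, matrix, tracheal and myoblast counts were the same over the list alone. Adjusted p-values of the genes given with values for this class lay between 7.53e-05 and 0.00411. The median log2 fold change of all genes was -0.02 with TMM and -0.17 with library totals. With genes scaled over all libraries, Hsp68, Hsp70Aa, Hsp27, stg, Hex-A and aop turned direction and bi and sty lost their calls (0.63 and 0.13), and thinning to 2000 UMIs ended those of sty and aurB. Without mutant replicate 1 the value of hid was 1.02.

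In epithelium outside the blastema-like class, 5797 of 10391 genes passed, with 3227 higher and 2570 lower in mutants. There Wnt4 rose from 2.54 and 2.74 CPM to 16.7 and 14.7 CPM (2.57 ± 0.21) and Ldh, lactate dehydrogenase, from 3.92 and 3.84 CPM to 10.9 and 8.72 CPM (1.34 ± 0.24), a call lost without control replicate 1 (1.29) or 2 (1.27). Of 19 ligands and proteases, 12 rose and 1 fell, the same over the list alone (list adjusted p = 0.00367 preset, adjusted p = 0.442 with an estimated correlation). The ecdysone list had 16 higher and 0 lower of 19 (16 and 1 over the list alone; list adjusted p = 6.50e-12 preset, adjusted p = 0.442 with an estimated correlation). The counts were 2568 without control replicate 1 and 2501 without control replicate 2.

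The comparison of blastema-like with other epithelium within control libraries asked what marks the regenerating cells, with chemistry the same on both sides. Only members of lists kept out of the clustering are reported, and genes used to name the class are left out. Wnt ligand genes were strongly higher in blastema-like cells. Wnt4 was at 116 and 133 CPM against 2.67 and 2.74 CPM in other epithelium, a log2 fold change of 5.53 ± 0.16. Wnt6 and wg were higher by 3.72 ± 0.14 and 3.44 ± 0.14, upd2 by 5.69 ± 0.32 and Ets21C by 3.33 ± 0.21. Of 16 ligands and proteases, 11 were higher and 2 lower, the same over the list alone (list adjusted p = 1.43e-11 preset, adjusted p = 0.299 with an estimated correlation). Of 20 JNK and stress genes, 8 were higher and 1 lower, the same over the list alone, with aspr at 4.85 ± 0.46, moody at 3.52 ± 0.33 and the protease homologue scaf at 2.03 ± 0.13 (list adjusted p = 0.000355 preset, adjusted p = 0.299 with an estimated correlation). The cell death genes hid and rpr were higher by 2.03 ± 0.13 and 1.84 ± 0.13, and apoptosis genes had 5 higher and 2 lower of 12 (5 and 3 over the list alone; list adjusted p = 0.00958 preset, adjusted p = 0.339 with an estimated correlation).

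Several metabolic and hormonal genes set blastema-like cells of controls apart. Of 14 glycolysis genes, 11 were lower and 1 higher, the same over the list alone: Ldh was higher by 3.86 ± 0.18, while Gapdh2, Ald1 and Pglym78 were lower at -1.48 ± 0.12, -1.21 ± 0.14 and -1.31 ± 0.15 (list adjusted p = 0.00149 preset, adjusted p = 0.299 with an estimated correlation). ImpE1, an ecdysone-inducible gene, was higher by 3.86 ± 0.14, and ImpE2, Syp and br were lower at -3.19 ± 0.17, -1.57 ± 0.12 and -1.26 ± 0.13 (2 higher and 7 lower of 17 list members, the same over the list alone; list adjusted p = 0.278 preset). EGFR feedback genes had 7 lower and 0 higher of 8, the same over the list alone, with kek1 at -1.60 ± 0.13 and aos at -1.56 ± 0.25 (list adjusted p = 0.00958 preset, adjusted p = 0.299 with an estimated correlation). S phase genes had 9 lower and 0 higher of 12 (11 and 1 over the list alone; list adjusted p = 0.0362 preset, adjusted p = 0.735 with an estimated correlation), with RnrS, a ribonucleotide reductase subunit, at -0.88 ± 0.14. The small heat shock gene Hsp27 was at -1.20 ± 0.11, in a list with 8 lower and 1 higher of 15 (9 and 1 over the list alone; list adjusted p = 0.0139 preset, adjusted p = 0.524 with an estimated correlation). With legacy set to FALSE, the counts of higher and lower genes in this comparison were 11 and 2 for ligands, 6 and 1 for JNK and stress, 5 and 2 for apoptosis, 1 and 11 for glycolysis, 1 and 7 for ecdysone, 0 and 6 for EGFR feedback, 0 and 4 for S phase and 0 and 8 for heat shock genes. SPARC rested on 1 library, at 303 and 20.9 CPM in the blastema-like cells of control replicates 1 and 2 against 73.2 and 30.2 CPM elsewhere, and its direction turned without control replicate 1 (-0.57). The fit called 2612 of 8981 genes (749 higher, 1863 lower), DESeq2 1411 (791 higher, 620 lower), and leaving out control replicates 1 and 2 gave 1430 and 1530. These totals include genes used in the clustering, so they do not measure what marks the class. The median of all genes was -0.24 with TMM and -0.04 with DESeq2. Adjusted p-values with the edgeR option legacy set to FALSE lay between 8.45e-09 and 0.00583 for the genes named here other than SPARC (0.101), and thinning ended the calls of Pglym78 and aos.

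The class by genotype interaction asked whether blastema-like cells differed from other epithelium by another amount in mutants than in controls, a comparison in which a fixed factor per gene between chemistries cancels. The JAK/STAT ligand genes upd1 and upd2 were lower in mutant blastema-like cells relative to other epithelium. The upd1 level was 40.5 and 44.3 CPM in blastema-like cells and 5.96 and 6.55 CPM in other epithelium of controls, against 0.920 and 0 and 7.14 and 4.47 CPM in mutants, an interaction log2 fold change of -6.02 ± 0.63. For upd2 it was -4.36 ± 0.56, with 92 and 251 UMIs in control and 11 and 0 UMIs in mutant blastema-like cells. Fitted values at such low counts depend on the prior count, and their SE can be smaller than counting error. Thinning cells to 2000 UMIs ended the upd2 call, at -3.92. Without mutant replicate 1, which held every mutant UMI of both genes in the class, the fits gave -14.23 for upd1 and -14.06 for upd2. Mmp1, matrix metalloproteinase 1, changed by -2.04 ± 0.19: its levels in blastema-like cells were 345 and 342 CPM in controls and 319.6 and 167 CPM in mutants, and in other epithelium 21.1 and 24.7 CPM and 78.8 and 52.9 CPM, so that its interaction went with a rise outside the class, while its difference inside the class did not pass. Such a split into inside and outside rests on direct comparisons of the groups, in which chemistry cannot be told apart from genotype. Of 19 ligands and proteases, 9 were lower and 1 higher (10 and 1 over the list alone). The 19 include Mmp1, Ilp8 and upd3, which served to name the class and were left out of the list in the comparison within controls. The list adjusted p was 4.89e-12 in camera with a preset correlation (adjusted p = 0.323 with an estimated correlation) and 0.0437 in fry. Adjusted p-values with legacy set to FALSE were 0.000723, 0.000766 and 0.000762 for upd1, upd2 and Mmp1, of which Mmp1 also served to name the class.

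**Figure D2:**
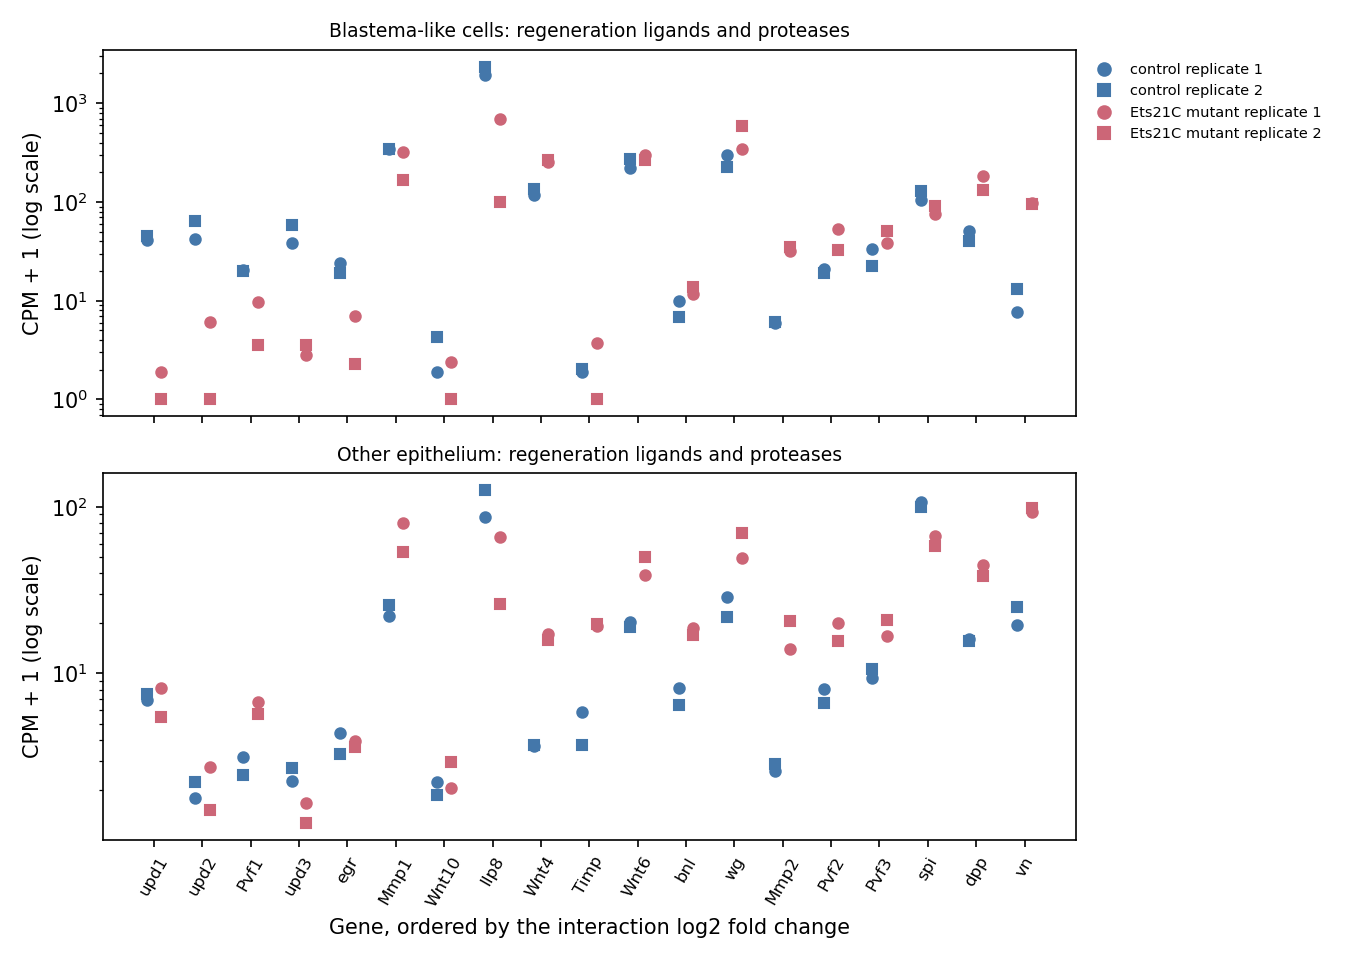
Level of each measured gene of the regeneration ligand and protease list in blastema-like cells and in other epithelium, as CPM plus 1 on a log axis, with 1 point per library (circles for replicate 1, squares for replicate 2). Control blastema-like cells lie at 40.5 and 44.3 CPM for upd1, and mutant ones at 0.920 and 0 CPM, while 9 of the 19 genes were lower and 1 higher in the interaction.

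Single genes outside the ligand list also had an interaction. Of the genes in this paragraph, only ImpE1, kek1, Ilp8 and Ets21C were kept out of the clustering, and the others could help define the class. PGRP-SA (-3.83 ± 0.41) and the gene FBgn0031629 (-2.63 ± 0.19) were lower in mutant blastema-like cells relative to other epithelium, FBgn0031629 at 763 and 579 CPM in controls and 109 and 63.7 CPM in mutants. ImpE1 was at 311 and 296 CPM in control and 529.7 and 404 CPM in mutant blastema-like cells, and at 20.8 and 20.9 and 237 and 426 CPM in other epithelium, so that its interaction (-3.29 ± 0.18) went with a rise outside the class. The cuticle gene TwdlE (5.13 ± 0.40), the disc genes tinc (3.74 ± 0.49) and CG4374 (3.72 ± 0.46), and Gasp (2.09 ± 0.20) were relatively higher in mutant blastema-like cells. So was asRNA:bsAS (3.30 ± 0.38), whose reads may not be told apart from those of its antisense partner bs. The EGFR inhibitor kek1 changed by 1.25 ± 0.18, the proneural gene sc by 2.29 ± 0.33, Delta by 0.94 ± 0.19, the homeobox gene hth by 1.07 ± 0.15, kirre by 2.68 ± 0.49, tsh by -1.94 ± 0.39 and the odd-skipped family gene drm by -5.15 ± 0.71, a call lost without control replicate 2 (-3.98) and a value of -13.99 without mutant replicate 1. Without control replicate 2, sc was at 3.77. For tsh, blastema-like cells held 5.78 and 6.87 CPM in controls and 6.90 and 6.37 CPM in mutants, a ratio of mutant to control UMIs of 1.01 (0.561 to 1.77), against 32.0 and 34.9 CPM and 132 and 142 CPM in other epithelium, so that its interaction went with a rise outside the class. As for Mmp1, the rises of ImpE1 and tsh outside the class are direct comparisons, which a chemistry factor per gene would also move. Blastema-like cells gave 3 and 21 drm UMIs in controls and 2 and 0 in mutants, a ratio of 5.93 (1.47 to 51.7). Adjusted p-values of these 15 genes lay between 0.000762 and 0.0435 with legacy set to FALSE. A robust prior ended the calls of TwdlE, FBgn0031629, Sp1 and Ilp8, and with both options also those of ImpE1 and sc. Ilp8, a relaxin-like hormone gene that delays metamorphosis, was at 1917 and 2346 CPM in control and 687 and 99.3 CPM in mutant blastema-like cells (-1.50 ± 0.17, adjusted p = 0.0703 with legacy set to FALSE). Without mutant replicates 1 and 2 the Ilp8 value was -2.36 and -0.93. Sp1, with 3 and 1 UMIs in control and 278 and 113 UMIs in mutant blastema-like cells (5.61 ± 0.54), had an adjusted p of 0.0576 with that option, and for Ets21C itself the value was -0.24 ± 0.31 (adjusted p = 0.783), or 0.05 without control replicate 1 and 0.27 without mutant replicate 1.

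Among the remaining lists, pouch genes and hinge and notum genes had the most members with an interaction. Like the Wnt and Hippo, immune and cell type marker lists, they were not kept out of the clustering, so their genes could help define the class. With counts of higher and lower genes, and in brackets those adjusted over the list alone, the ecdysone list had 2 and 2 of 17 (5 and 3), pouch genes 6 and 2 of 22 (10 and 2), and hinge and notum genes 4 and 2 of 15 (5 and 6). EGFR feedback genes had 2 and 0 of 8 (3 and 0), glycolysis 1 and 1 of 14 (1 and 1), the Wnt and Hippo list 1 and 0 of 11 (3 and 0), and JNK and stress genes 1 and 0 of 23 (4 and 1). The last list holds puc, rgn and Gadd45, which served to name the class. JAK/STAT genes had 0 and 1 of 7 (0 and 1), immune genes 0 and 1 of 8 (0 and 1), matrix genes 0 and 1 of 9 (1 and 1), G2 and mitosis 1 and 0 of 13 (1 and 0), and the sex list 1 and 0 of 2 (1 and 0). Myoblast markers had 1 and 0 of 8 (1 and 1) and tracheal markers 1 and 0 of 5 (1 and 0). Apoptosis, S phase, cell cycle arrest, heat shock, hemocyte and neural lists had 0 and 0 (0 and 0) of 12, 12, 5, 15, 6 and 5. With legacy set to FALSE, higher and lower counts were 0 and 7 for ligands, 0 and 1 for ecdysone, 2 and 0 for pouch, 1 and 1 for hinge and notum, 1 and 0 for EGFR feedback and 0 and 1 for immune genes, 1 and 0 for myoblast and for tracheal markers, and 0 and 0 for the other lists. No list other than the ligands passed in camera with a preset correlation (adjusted p from 0.153 to 0.969), and fry also called tracheal markers (adjusted p = 0.0437). Of 8981 genes, 260 passed with the fixed options (145 higher, 115 lower), 77 with legacy set to FALSE (34 higher, 43 lower) and 103 in DESeq2 (29 higher, 74 lower). Scaling by library totals gave 79 higher and 129 lower, cells thinned to 2000 UMIs gave 3 higher and 34 lower, and without control replicate 2 the count was 167. The median of all genes was 0.16 with TMM and -0.06 with DESeq2. With genes scaled over all libraries, kirre, kek1 and hth turned direction and sc and Delta lost their calls, as did Sp1. Thinning turned drm and ended the calls of Sp1, PGRP-SA, CG4374, tinc, Gasp, asRNA:bsAS, kirre, kek1, hth, sc, Delta and tsh, besides upd2.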

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

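The interaction and the fits with 1 library left out were planned, while the tests of intron length, matched lists, list share in the interaction and mixing, and the edgeR fits with legacy set to FALSE, were chosen after the results were seen, as were the bounds used to weigh each test. The differences between the 2 genotypes in the class effect, tested as the interaction in edgeR, drew attention for 37 genes. These are calls with the default options, whose p-values are too small in this fit. With legacy set to FALSE, Ilp8, Sp1, Socs36E, Ldh, Gapdh2, SPARC, stg, Xrp1, ds and lncRNA:roX1 did not pass. Neither did Hr4, Eip75B, ImpE2, ct, dve, mirr, ara and sty, and for Ect3 no value with that option is given. Interaction log2 fold changes were lower, with a fall inside the class, for upd1 (-6.02), upd2 (-4.36), PGRP-SA (-3.83), FBgn0031629 (-2.63), Ilp8 (-1.50) and SPARC (-1.07), of which Ilp8 and SPARC did not pass inside the class in DESeq2. They were lower with a rise outside the class, and no difference inside it that passed, for Mmp1 (-2.04), Socs36E (-0.74), Ldh (-1.07), ct (-1.44) and tsh (-1.94). Falls and rises inside or outside the class are direct comparisons of the groups, in which chemistry cannot be told apart from genotype. ImpE1 (-3.29) and Hr4 (-1.80) rose inside the class and more outside it, Hr4 with 7 and 3 UMIs in control and 116 and 149 UMIs in mutant blastema-like cells. Lower values were also seen for drm (-5.15), which rose outside the class, and Ect3 (-3.78), which did not pass there; neither was tested inside it. Thinning to 2000 UMIs ended the upd2 call, at -3.92. Ect3 gave 3 and 21 UMIs in control and 1 and 0 UMIs in mutant blastema-like cells, a ratio of 11.9 (1.93 to 488). Leaving out control replicate 1 turned SPARC (0.46) and ct (0.44). Higher values were seen for Sp1 (5.61), TwdlE (5.13), tinc (3.74), CG4374 (3.72), asRNA:bsAS (3.30), kirre (2.68), Gasp (2.09), dve (2.61), sc (2.29), mirr (1.86), ara (1.47), kek1 (1.25), hth (1.07) and Delta (0.94). Smaller higher values were those of Eip75B (0.88), ds (0.83), ImpE2 (0.79), sty (0.75), Gapdh2 (0.70), stg (0.62), Xrp1 (0.58) and lncRNA:roX1 (0.57). Outside the class Gapdh2 and Gasp fell, and inside it Gasp rose and Gapdh2 did not pass. Calls were lost without control replicate 1 for Hr4 (-1.24), Socs36E (-0.40), stg (0.48), dve (2.43) and ara (0.82), and without control replicate 2 for drm (-3.98), Ect3 (-1.82), Hr4 (-2.17), Ldh (-0.74), Xrp1 (0.25), ImpE2 (0.73), ds (0.68), sty (0.60), lncRNA:roX1 (0.54) and dve (2.83). They were lost without mutant replicate 1 for Ect3 (-11.62), Ldh (-0.69), SPARC (-1.22), Xrp1 (0.44), ImpE2 (0.24), sty (0.68), lncRNA:roX1 (0.50), dve (2.69) and ara (1.61), and without mutant replicate 2 for ct and Ect3 (-3.29), Hr4 (-1.70), Socs36E (-0.54), SPARC (-1.02), Xrp1 (0.74), stg (0.23), Gapdh2 (0.39), sty (0.84) and lncRNA:roX1 (0.65). Called values that moved by over 1.5 times were, without control replicate 1, Xrp1 (0.88) and mirr (1.07), without control replicate 2, SPARC (-2.20), Socs36E (-1.14), sc (3.77), mirr (5.51) and ara (2.79), without mutant replicate 1, upd1 (-14.23), upd2 (-14.06), drm (-13.99), Ilp8 (-2.36), stg (1.09) and Gapdh2 (1.07), and without mutant replicate 2, Ilp8 (-0.93) and ImpE2 (1.32); ct ranged from -4.00 to 0.44.

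Genotype differences in epithelium were related to intron length. If reads of long or intron-rich genes were counted more in mutants, the log2 fold change would follow intron length, and Spearman's rho over 10352 genes, which are not independent replicates, was 0.259. Among the fifth of genes with the shortest introns 51.7% passed, 524 higher and 547 lower, which argues against length as the whole cause there. Over the other genes as a whole length and genotype cannot be told apart, since chemistry and software changed with genotype. The medians of the ecdysone, Wnt and Hippo and heat shock lists stood at percentiles 100, 99.64 and 98.86 of length-matched lists, which argues against length as the whole cause for those lists. Matched genes were drawn singly, whereas list members vary together (estimated correlations 0.274, 0.314 and 0.536). These percentiles therefore overstate how far the lists stand out. The Ets21C genotype stays open as well, and was not tested apart from length, chemistry and software.

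Ecdysone and timing genes were higher in mutant epithelium, with a list median of 2.79. That median lay at percentile 100 of 10000 random lists matched on intron length and level, whose central 95% ran from 0.75 to 1.90, which argues against length as the whole cause. The limit given above, that matched genes were drawn singly, holds for this percentile too. In the interaction 23.5% of the list passed, and 1 gene of 17 with legacy set to FALSE. Chemistry and software cannot be told apart from genotype for these genes, and a difference in developmental stage may contribute by either route.

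Regeneration ligands were lower in blastema-like mutant cells relative to other epithelium. Within the class 6 were higher and 6 lower in mutants (list median 0.27), and outside it 12 rose and 1 fell (median 1.32). A fixed factor per gene between chemistries would move both of these comparisons, so they do not show where the difference lay. The list holds Mmp1, Ilp8 and upd3, which also served to name the class. A fixed factor per gene between chemistries cancels in the interaction, where 7 ligands were lower with legacy set to FALSE, which argues against it; an effect of chemistry that differs between classes stays open. Without mutant replicate 2, whose class held 29 cells, the list median of the interaction was -0.86, against -1.37 with all libraries. The direction of the list thus did not rest on that library alone. That fit holds 1 mutant library and its spread comes from the controls, so it gives no test of the ligands. Other epithelium of average composition may have been mixed into the mutant class in 1 share per library. Ligands with at least 10 UMIs had a mean squared departure from 1 share of 11.9 squared SE in mutant replicate 1 (12 ligands). The departure was 10.4 in mutant replicate 2 (9 ligands), against at most 2.19 in 20 simulated mixtures with a share of 60%. Each of these fits also holds 1 mutant library, so its SE comes from the spread of the controls. The simulated mixtures gave a median share of 67.5% where 60% was put in. The departures therefore do not decide whether such mixing was the whole cause. A part of other epithelium with its own ligand levels stays a candidate explanation, since genes of other lists high in the class had a median of -1.05 against -1.50 for ligands, a gap of 0.45 (95% bootstrap interval -1.36 to 2.0) that decides nothing, and a dependence of these ligands on Ets21C, in or outside the class, may also hold.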

How the results depend on the processing

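The 3 sets of edgeR options and the fit without shallow or deep clusters were added after the data were seen, and the other alternatives were planned. Leaving out each library in turn gave 2597 to 6338 calls in epithelium, 2501 to 6198 in other epithelium, 1430 to 2897 for the class effect in controls and 167 to 271 for the interaction. Of the named gene results, 52 lost their call without control replicate 1, 52 without control replicate 2, 17 without mutant replicate 1 and 32 without mutant replicate 2. For Ets21C, leaving out libraries gave -1.30 to 0.37 in epithelium, -0.61 to 0.21 in blastema-like cells, -1.01 to 0.61 in other epithelium and -0.62 to 0.27 in the interaction. Ranges were -0.57 to 2.05 for SPARC in the class effect, and in the interaction -2.20 to 0.46 for SPARC, -0.16 to 0.84 for rpr, -0.17 to 0.12 for PCNA, -4.00 to 0.44 for ct and -0.28 to 0.30 for crq. DESeq2 gave 1643 calls in blastema-like cells, 1411 for the class effect and 103 for the interaction, and turned E2f1 (-0.013), Hsp26 (-0.036) and crq (-0.15) in the interaction. With legacy set to FALSE the interaction had 77 calls, all among the 260, and with a robust prior as well 93; Ets21C in other epithelium turned to -0.064 in both. Estimated correlations left 0 lists past the threshold in camera, in epithelium (8 with the preset correlation) and in the interaction (1), where fry called 2. In epithelium fry called 4 lists that camera with the preset correlation did not. They were G2 and mitosis (fry adjusted p = 0.0270), matrix (0.00684), neural (0.00684) and apoptosis genes (0.0376). Of the lists camera called there, fry did not call S phase (adjusted p = 0.146) or heat shock genes (0.135). The library totals setting turned crq (-0.077), no low-count filter PCNA (0.036), program genes kept in clustering PCNA (0.0094), and resolution 0.6 crq (-0.021). At least 1000 genes per cell turned Ets21C in blastema-like cells (0.0070) and PCNA in the interaction (0.062). At most 20% mitochondrial UMIs moved the blastema-like share of control replicate 2 to 1.74%, below the 2.44% of mutant replicate 1, and the myoblast-like share of mutant replicate 1 to 13.1%, and turned dap (-0.058), Hsp23 (-0.0045), Hsp26 (-0.13) and crq (-0.15). Doublet calls kept gave myoblast-like shares of 0.369% and 0.00858% in the mutants. Without shallow or deep clusters, Ets21C in other epithelium was -0.070 and crq -0.0018. The cause of these changes was not tested.

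Thinned to 2000 UMIs per cell, the counts were 3806 in epithelium, 531 in blastema-like cells, 3761 in other epithelium, 547 for the class effect and 37 for the interaction, where fewer UMIs and genes enter. Thinning turned Ets21C in epithelium (0.018) and, in the interaction, Ets21C (0.62), drm (4.56), Eip75B (-0.27), Hsp23 (-0.0085), Hsp26 (-0.14), crq (-0.66) and elav (-3.66). Genes scaled over all libraries gave 1426 calls in blastema-like cells and shares of 1.42% and 0.0432% in the mutants. In blastema-like cells it turned stg (-0.77), Hex-A (-0.62), Hsp68 (-1.14), Hsp70Aa (-0.21), Hsp27 (-0.059) and aop (-0.18). In the interaction it turned kirre (-0.80), PCNA (0.32), E2f1 (-0.85), stg (-1.51), dap (-0.76), ImpE2 (-0.26), Hsp23 (-1.62), Hsp26 (-1.44), kek1 (-0.14), sty (-0.89), hth (-0.20), ara (-0.49), He (-7.64) and elav (-0.79). The cause was not tested, and 98 of its 227 interaction calls were shared with the 260.

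Replicate numbers are shared between groups but nothing pairs the samples: the correlation of same-numbered deviations was -0.0105 over 6846 genes. With the replicate number as a block, 5679 genes passed in epithelium, 2453 in blastema-like cells and 5708 in other epithelium, and Ets21C in other epithelium turned to -0.079.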

Other observations

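All results in this part were chosen after the data were seen. The transcription factor gene chinmo, which marks early larval stages, fell in mutants: in epithelium it stood at 206 and 281 CPM in controls and 118 and 47.4 CPM in mutants (log2 fold change -1.56 ± 0.43 (SE), edgeR adjusted p = 0.0259), a call lost without control replicate 1 (-1.82) or 2 (-1.38), with -2.41 without mutant replicate 1. In blastema-like cells chinmo stood at 299 and 312 CPM in controls and 124 and 44.9 CPM in mutants (-1.77 ± 0.36, adjusted p = 0.00629), or -2.76 without mutant replicate 1. Of all mutant barcodes, 1126 and 2350 (13.4% and 14.1%) had at least 500 genes and over 10% mitochondrial UMIs, against 1 and 0 of the control barcodes. Barcodes under 500 genes were not counted here, whatever their mitochondrial share. Chemistry and the software that called the barcodes differed between the groups. Barcodes under 500 genes numbered 0 and 0 in controls and 1587 and 2651 in mutants. The difference is therefore no measure of cell damage by genotype.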
